A study of Mus musculus with 10 samples.

How the data were processed

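RNA from the cerebral cortex of C57BL/6 mice aged 3 months was sequenced in 10 libraries, 5 of control mice and 5 of mice in which Brap was conditionally knocked out (BrapcKO). Brap encodes the BRCA1-associated protein, also called IMP, a ubiquitin ligase known to bind the scaffold KSR and to restrain Ras to MAP kinase signalling. In the labels, flox marks a Brap allele with recombination sites for Cre recombinase, ko a deleted allele and wt the normal allele. The control group held 3 flox/wt Cre- and 2 flox/flox Cre- libraries, and the BrapcKO group held 3 flox/ko Cre+ and 2 flox/flox Cre+ libraries. The labels name neither the Cre driver nor the deleted exons. Every BrapcKO library was Cre+ and every control library Cre-, so an effect of Cre itself cannot be told apart from the knockout. They do not say in words that each library came from a separate animal, so the p-values measure the spread between these libraries, part of which may be technical.

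Per the labels' protocols, frozen cortex was extracted with Trizol, the RNA was treated with DNase, and libraries were built from total RNA after depletion of ribosomal RNA. Per the submitters' processing notes, FastQC, Subread, featureCounts, DESeq2 and edgeR were used, with the mouse builds mm10 and GRCm38; their versions, order and settings are not given in the sources used here. The deposited values are raw read counts per gene, 1 column per library, with no normalisation by the authors visible in the values. Whether reads were assigned by strand is not given in the sources used here, so reads from overlapping and antisense genes cannot be told apart, and reads shared between near-identical copies, such as protocadherins, ribosomal proteins and histones, may be divided among them. The table held 14276 genes, of which 14264 were protein coding, 7 were of another type and 5 identifiers had no match. All other identifiers, 14271, matched the GENCODE M21 annotation of GRCm38, 13492 of them in the same version, and symbols and coordinates were taken from it. Every gene had at least 0.582 CPM (counts scaled to the library total) in at least 5 libraries, so genes of low expression had been left out of the table, and ratios for genes near that level are less certain.

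Total counts per library ran from 17188901 to 28991874. The titles carry a code, B1 or B2, whose meaning the labels do not state. The 6 B1 libraries (2 control and 4 BrapcKO) held 17188901 to 20955211 counts and the 4 B2 libraries (3 control and 1 BrapcKO) held 26356508 to 28991874. At these depths a gene at 1 CPM rests on about 17.2 to 29 counts. Intervals and counts cover counting error and spread between libraries as the models estimate them.

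Counts were compared with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM normalisation, group as the only term) in R 4.3.3. The default low-count filter of edgeR removed 0 genes. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 is called a change. CPM values per gene use library totals scaled by TMM, except those of Y-linked genes and the level above, which use plain totals. Standard errors (SE) were computed as the log2 fold change divided by the square root of the F statistic. Adjusted p-values given without another name come from this edgeR test. Genotypes within each group were compared in a fit of 4 genotype groups over all 10 libraries. For 47 gene lists, the camera test of limma 3.58.1 was run on voom values with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data; fry, a rotation test of limma that allows for correlation, was an alternative. Intervals for list means come from a linear model of the mean log2 CPM of the list in each library. For each list the number of members that changed is given over all genes and also adjusted over the list alone.

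The groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. That rule takes Brap, then genes with an adjusted p under 0.05, an average log2 CPM of at least 0 and all 5 libraries of one group above all 5 of the other. Among those it takes the 10 largest rises and the 10 largest falls, then the 5 smallest p-values in each direction. From each list called by camera, and from the astrocyte, microglia, interferon, senescence, p53, repair, synapse and H2A ubiquitin lists in any case, it takes up to 4 members with the smallest p. Predicted genes are counted and not named. Every gene of the first parts of the rule is named; from some lists the text gives only part of the members taken, and counts over the named genes cover all that the rule took. Some genes that the rule or a flag took are not reported here. Genes named outside the rule are said to be so.

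Alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, the likelihood-ratio test of edgeR, other scalings and filters, a test against a fold of 1.2, 1 surrogate variable from sva 3.50.0, the title code as a term, the mean log2 CPM of Ddx3y, Uty, Kdm5d and Eif2s3y as a term (the Y-linked score), subsets by title code and genotype, and leaving out each library in turn. The fit with the title code and the Y-linked score together, the list tests with terms that allow for correlation, and the alternatives for the genotype comparisons, were chosen after seeing the data.

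The procedure was tested on simulated data with 200 changed genes among 14276, drawn from the means and library sizes of these libraries. For BrapcKO against control it recovered 31.3% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 90.9% of those changed 4-fold, with 3 false calls among 133. With the title code as a term it recovered 52.2%, 82.1% and 97% of them, with 11 false calls among 177. DESeq2 with group only recovered 47.8%, 77.6% and 93.9%, with 17 false calls among 177. DESeq2 was not run on simulated data for the genotype comparisons. In the same simulation camera called the list that had been changed but also 8 lists that had not, and 0 such lists with the title code as a term. The simulated genes varied independently apart from the title code, and no Y-linked difference was simulated. The simulation therefore does not show how often camera calls unchanged lists of correlated genes in these data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.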

Results

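The transcriptome of cerebral cortex was measured by sequencing of ribosomal RNA-depleted total RNA in 5 control and 5 BrapcKO libraries of mice aged 3 months. The comparison asked which genes differ in cortex between conditional Brap knockouts and control littermates. Total counts ran from 17188901 to 28991874 per library over 14276 genes. Libraries are named by group and by the number in their title. The title code split the libraries unevenly, with 2 control and 4 BrapcKO libraries in B1 and 3 control and 1 BrapcKO in B2. Reads from Y-linked genes were also uneven: Ddx3y stood at 119 to 147 CPM in control 23 and BrapcKO 05, 06, 07 and 21, and at no more than 0.053 CPM in the other libraries. Uty, Kdm5d and Eif2s3y were high in the same libraries. The labels give no sex, but these reads mark those libraries as male and the others as female, so sex was uneven between the groups. Values with the title code, or with the title code and the Y-linked score, as terms are therefore given beside many of the results. No pair of replicates was a repeated library: chi-square per degree of freedom between replicates ran from 7.15 to 96.29.

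Brap itself was not lower in the libraries labelled BrapcKO. Brap (ENSMUSG00000029458.14, GRCm38 chromosome 5, 121660563 to 121687256, plus strand) stood at 88.1, 94.3, 76.7, 84.2 and 98.6 CPM in control 08, 09, 22, 23 and 24. It stood at 109.9, 89, 100.9, 110.5 and 108.8 CPM in the libraries labelled BrapcKO 04, 05, 06, 07 and 21. The means were 88.4 ± 8.58 and 104 ± 9.15 CPM (SD, n = 5 each), a log2 difference of 0.23 (SE 0.09, 95% interval 0.02 to 0.44). The edgeR adjusted p was 0.2 over all genes, and a two-sided exact permutation test of Brap alone gave p = 0.0317 over 252 arrangements. The difference was 0.23 with the title code as a term and 0.30 with both terms (adjusted p 0.18 and 0.3). Between the flox/flox Cre+ and flox/flox Cre- libraries it was -0.03, and between flox/ko Cre+ and flox/wt Cre- libraries 0.40 (adjusted p 0.99 and 0.089). The table has 1 count per gene, which does not show loss of part of a gene, so the knockout labels were not checked by this value and every direction below rests on the labels.

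In the libraries labelled BrapcKO 617 genes changed, of which 261 were higher and 356 lower. Of these, 108 were higher and 78 lower by more than 2-fold. In 214 of the higher and 322 of the lower genes all 5 libraries of one group lay above all 5 of the other. Over all genes the groups were apart in 6.8%, against 0.794% given by chance without regard to the filter. The table kept only genes with at least 0.582 CPM in at least 5 libraries. Where all 5 libraries of one group lay below that level, the other 5 had to lie above it. For such genes the separation was fixed in advance. With library size as the only scaling, 302 genes were higher and 275 lower (52.3% higher, against 42.3%). The title code as a term gave 1152 calls and both terms 322, of which 594 and 213 were among the 617. All 617 genes had the same direction in each of these fits. They were picked for their difference in these same libraries, so the shared direction is little support. The Y-linked score alone gave 94 calls, 92 of them among the 617, and 92 genes were called in the main fit and all 3 fits with terms. With group in the model, 4 genes rose and 0 fell with the Y-linked score itself. The loss of calls with this score therefore does not show that many genes follow it. Without 1 library the main count of 617 fell to 275 (without control 23), 303 (BrapcKO 07), 363 (BrapcKO 06), 395 (control 22) or 400 (control 09).

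Genes induced by neuronal activity were lower in the libraries labelled BrapcKO. Of the 25 immediate early genes measured, 16 fell and 0 rose, and adjusted over the list alone 19 fell and 1 rose. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273), a transcription factor induced within minutes of stimulation, fell from 77 ± 21.4 to 15 ± 4.15 CPM (n = 5 each; log2 fold change -2.36, SE 0.23, adjusted p 0.00082). Arc, which acts at synapses in the trafficking of glutamate receptors, fell from 491 ± 161 to 137 ± 27.1 CPM (-1.84, SE 0.24, adjusted p 0.0029). Egr2, Npas4 and Nr4a2, transcription factors of the same response, changed by -2.45, -2.19 and -1.12 (adjusted p 0.0023, 0.011 and 0.0024). The median over the list was -1.16 (camera adjusted p 5.4e-11, and adjusted p = 0.3 with an estimated correlation). With the title code as a term the median was -1.19 and with both terms -1.18 (camera adjusted p 1.7e-09 and 7.1e-12). With both terms Npas4 differed by -2.20, with an adjusted p of 0.063.

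**Figure D1:**
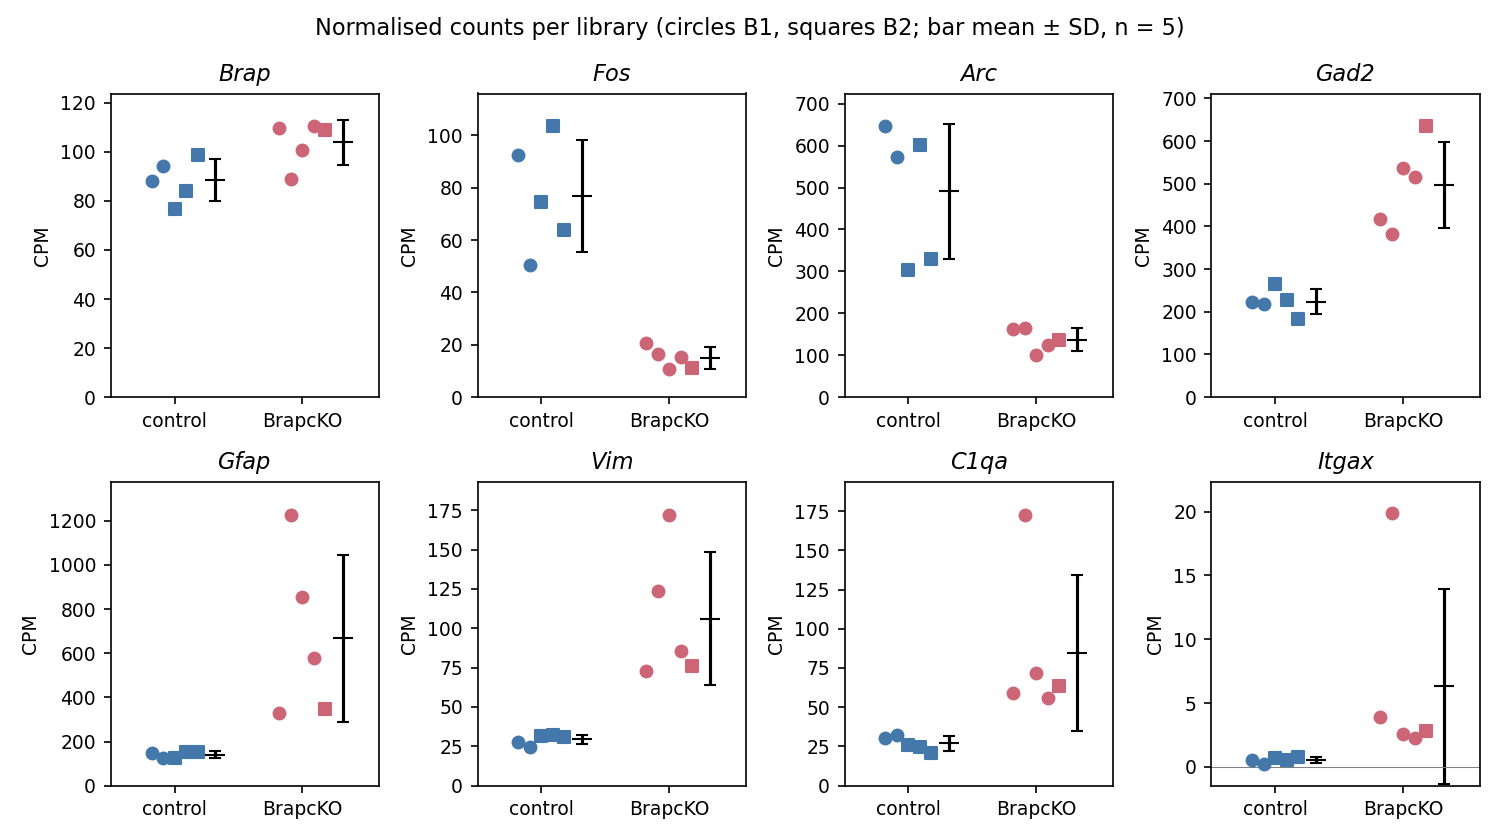
Expression of Brap, Fos, Arc, Gad2, Gfap, Vim, C1qa and Itgax in CPM (linear axis, a scale of its own for each gene) in each library, by group, with circles for B1, squares for B2, and bars for the mean and SD of 5 libraries per group. Fos and Arc are lower in every library labelled BrapcKO than in every control library, and Brap overlaps between groups.

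Genes of reactive astrocytes were higher in the libraries labelled BrapcKO. Of the 20 measured, 9 rose and 0 fell, and 15 rose when adjusted over the list alone. Gfap (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, rose from 141 ± 14.3 to 667 ± 380 CPM (2.25, SE 0.35, adjusted p 0.009). Vim, another intermediate filament, rose from 29.4 ± 3.04 to 106 ± 42.2 CPM (1.85, SE 0.23, adjusted p 0.0023). Osmr, a subunit of the oncostatin M receptor, and Serpina3n, a secreted protease inhibitor, rose by 1.37 and 1.65 (adjusted p 0.0091 and 0.0094). The list median was 0.93 (camera adjusted p 2.3e-10, and adjusted p = 0.3 with an estimated correlation), and 0.74 with both terms (camera adjusted p 2.1e-05). The 20 general astrocyte markers had 0 changed members and a median of 0.10 (camera adjusted p 0.17; 0.14 and 0.044 without BrapcKO 21). With both terms Gfap, Osmr and Serpina3n differed by 1.41, 0.99 and 1.19 (adjusted p 0.19, 0.06 and 0.18), and Vim by 1.47 (adjusted p 0.049).

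Microglial and complement genes were also higher. Of 22 genes of disease-associated microglia 3 rose and 0 fell, and 12 rose when adjusted over the list alone. Gpnmb, a membrane glycoprotein, and Lyz2, a lysozyme, rose by 1.89 and 1.78 (SE 0.24 and 0.34, adjusted p 0.0023 and 0.017). Itgax, the integrin CD11c, rose from 0.536 ± 0.202 to 6.3 ± 7.65 CPM (3.51, SE 0.71, adjusted p 0.024). Spp1, osteopontin, differed by 2.23 (SE 0.58) with an adjusted p of 0.063; it was called without BrapcKO 05 or 21 (adjusted p 0.046 and 0.042). Of 12 complement genes 6 rose and 0 fell; adjusted over the list alone 8 rose and 1 fell. The receptor C3ar1 rose by 2.29, C1qa and C1qc, subunits of the first component, by 1.65 and 1.74, and C3 by 2.14 (adjusted p 0.014, 0.019, 0.026 and 0.021). The list medians were 1.17 for disease-associated microglia and 0.94 for complement (camera adjusted p 2.5e-06 and 0.00015; adjusted p = 0.53 and 0.3 with an estimated correlation). With both terms they were 0.57 and 0.95 (camera adjusted p 0.0014 and 0.00043), and Gpnmb differed by 1.52 (adjusted p 0.024); Lyz2, Itgax, C3ar1, C1qa and C3 differed by 1.14, 2.81, 1.49, 1.14 and 1.54 (adjusted p 0.24, 0.28, 0.19, 0.26 and 0.25), and the adjusted p of C1qc was 0.32 and that of Spp1 0.69 (0.81). The size of the microglial difference rested in part on BrapcKO 05, without which the disease-associated median was 0.44 (camera adjusted p 7e-08). Without BrapcKO 05 Itgax was 2.40 (adjusted p 0.0038). Itgax lost its call without control 08, 09, 22 or 23 (adjusted p 0.057 to 0.073). C1qc lost it without any 1 of the 5 controls (0.054 to 0.063), and C1qa and C3 without control 23 (0.057 and 0.052).

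Homeostatic microglia genes and interferon-stimulated genes were also higher as lists by camera, but fry did not call them (adjusted p 0.21 and 0.33). With the title code as a term, 11 and 26 of 60 arrangements of the libraries within the codes gave medians at least as large in absolute size. Of 20 homeostatic genes 1 rose, also when adjusted over the list alone: Ctss, the protease cathepsin S (1.36, adjusted p 0.032). Ptprc, Inpp5d and Tmem119 differed by 1.43, 0.62 and 0.39 (adjusted p 0.091, 0.15 and 0.15). Ptprc was called without BrapcKO 05 or 21 (0.82 and 1.62, adjusted p 0.044 and 0.043), and without BrapcKO 05 Inpp5d was 0.37. Of 34 interferon-stimulated genes 1 rose, Trim30a (2.46-fold, adjusted p 0.041), and 0 when adjusted over the list alone. Gbp3, Eif2ak2 and Oasl2 differed by 0.86, 0.53 and 1.02 (adjusted p 0.098, 0.11 and 0.12); Gbp3 and Oasl2 were 0.56 and 0.61 without BrapcKO 05. The medians were 0.65 and 0.52 (camera adjusted p 2.9e-05 and 0.00025; adjusted p = 0.6 and 0.66 with an estimated correlation). With both terms they were 0.33 and 0.11 (camera adjusted p 0.036 and 0.6), with Ctss at 0.86 and Trim30a at 0.77 (adjusted p 0.4 and 0.41). Without BrapcKO 05 they were 0.30 and 0.25 (camera adjusted p of the interferon list 0.011). Ctss lost its call without any 1 of the 5 controls or BrapcKO 06 (adjusted p 0.051 to 0.08), and Trim30a without any 1 of the 5 controls or BrapcKO 04, 06 or 07 (0.057 to 0.1).

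Genes of the synapse were lower by a small amount. Of 40 measured, 4 fell and 0 rose, and 6 fell when adjusted over the list alone. Rims1, an organiser of the presynaptic active zone, fell from 496 ± 66.9 to 291 ± 29.3 CPM (-0.77, SE 0.11, adjusted p 0.0037). Stx1a, a SNARE protein of vesicle fusion, changed by -0.74, Syt1, the calcium sensor of release, by -0.31, and Cplx2, a complexin, by -0.56 (adjusted p 0.0092, 0.029 and 0.038). The list median was -0.15 (camera adjusted p 0.0025, and adjusted p = 0.4 with an estimated correlation), and with both terms the camera adjusted p was 0.00028, with Stx1a, Syt1 and Cplx2 at -0.53, -0.32 and -0.45 (adjusted p 0.14, 0.089 and 0.28). With the Y-linked score as a term the median was -0.09 (camera adjusted p 0.032), and without BrapcKO 21 it was -0.08 (camera adjusted p 0.022). Syt1 lost its call without control 08, 09 or 23 or BrapcKO 06 or 07 (adjusted p 0.06 to 0.075). Cplx2 lost it without any 1 of the libraries except control 24 and BrapcKO 07 (0.05 to 0.092).

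Markers of upper cortical layers and of inhibitory neurons moved in both directions. Of 15 markers of upper-layer excitatory neurons 3 fell and 1 rose, and adjusted over the list alone 5 fell and 3 rose. Lamp5, a membrane protein of the LAMP family, fell from 104 ± 18.7 to 40.6 ± 9.74 CPM (-1.36, SE 0.17, adjusted p 0.0023). Plcxd2 and the transcription factor Lhx2 changed by -0.76 and -0.56, and the cadherin Cdh13 by 0.47 (adjusted p 0.013, 0.03 and 0.039). The median was -0.26 (camera adjusted p 0.026, and adjusted p = 0.3 with an estimated correlation), -0.38 with the title code and -0.40 with both terms (camera adjusted p 0.0088 and 0.018), and -0.20 with the Y-linked score alone, where the list was not called (camera adjusted p 0.084). With both terms Lhx2 and Cdh13 differed by -0.43 and 0.58 (adjusted p 0.25 and 0.1). The list was not called without control 09 or BrapcKO 21 (camera adjusted p 0.07 and 0.057). Lhx2 lost its call without control 22 or 23 or BrapcKO 06, 07 or 21 (adjusted p 0.052 to 0.081), and Cdh13 without any 1 of the libraries except control 24 and BrapcKO 05 (0.05 to 0.1). Of 21 inhibitory neuron markers 3 rose and 1 fell, 4 and 1 when adjusted over the list alone, with a median of 0.12 (camera adjusted p 0.083, and 0.03 without BrapcKO 05). Gad2, which makes GABA from glutamate, rose from 224 ± 29.1 to 498 ± 100 CPM (1.15, SE 0.14, adjusted p 0.0023). Cort, the neuropeptide cortistatin, fell from 2.7 ± 1.06 to 0.582 ± 0.0366 CPM (-2.21, SE 0.28, adjusted p 0.0023). Of 18 deep-layer markers 1 rose and 2 fell, 1 and 4 when adjusted over the list alone (median -0.19, camera adjusted p 0.091, and 0.031 without control 09).

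Markers of striatum, the region beneath cortex, were higher as a list by camera, but fry did not call them (adjusted p 0.33). Of 15 measured 2 rose and 0 fell, and 5 rose when adjusted over the list alone. Penk, the precursor of enkephalins, rose from 118 ± 38 to 273 ± 103 CPM (1.21, SE 0.28, adjusted p 0.04), and Rgs9, a regulator of G-protein signalling, by 0.86 (adjusted p 0.039). Pde10a and Isl1 differed by 0.54 and 1.14 (adjusted p 0.073 and 0.1, and Pde10a 0.027 without control 22). The median was 0.54 (camera adjusted p 0.00088, and adjusted p = 0.66 with an estimated correlation) and 0.61 with the title code as a term (camera adjusted p 1.9e-08). The list means of single libraries overlapped, at 4.04 to 5.46 log2 CPM in control and 4.9 to 5.79 in BrapcKO. With both terms Rgs9 differed by 1.00 (adjusted p 0.07). Penk lost its call without control 08, 09, 23 or 24 or BrapcKO 06, 07 or 21 (adjusted p 0.057 to 0.098). Rgs9 lost it without any 1 of the libraries except control 22 and BrapcKO 06 (0.057 to 0.098). Gad2, given above, is abundant in striatal neurons too.

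Targets of MAP kinase signalling, the pathway Brap is known to restrain, were lower where they changed. Of 28 genes 4 fell and 0 rose, and 6 fell when adjusted over the list alone. Etv1 and Etv5, transcription factors induced by the pathway, changed by -0.68 and -0.82 (SE 0.10 and 0.14, adjusted p 0.0047 and 0.011). Dusp6, a phosphatase that inactivates ERK, fell from 114 ± 17.9 to 63.2 ± 8.9 CPM (-0.85, SE 0.13, adjusted p 0.0054), and Phlda1 changed by -0.98 (adjusted p 0.044). The median was -0.11 (camera adjusted p 0.036, and adjusted p = 0.31 with an estimated correlation), and with both terms the camera adjusted p was 0.077, with Phlda1 at -0.78 (adjusted p 0.082). With the Y-linked score alone the median was -0.04 (camera adjusted p 0.11). The list was not called without control 08 or 09 or BrapcKO 05 or 06 (camera adjusted p 0.052 to 0.085), and its median was -0.07 without control 24 and -0.17 without BrapcKO 21. Phlda1 lost its call without any 1 of the libraries except control 08 and 09 and BrapcKO 21 (adjusted p 0.077 to 0.13).

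The clustered protocadherins, adhesion proteins of neurons encoded in tandem, had 0 changed members among 54. Pcdhac1 and Pcdhga9 differed by -0.67 and -0.44 (adjusted p 0.063 and 0.1, and Pcdhac1 0.034 without BrapcKO 05). The median was -0.16 (camera adjusted p 0.0011, and adjusted p = 0.6 with an estimated correlation). With both terms it was -0.26 (camera adjusted p 1.1e-06). Without control 09 it was -0.10, and without BrapcKO 21 it was -0.09 and the list was not called (camera adjusted p 0.13). The 22 genes of mature oligodendrocytes and myelin also had 0 changed members, with a median of -0.27 (camera adjusted p 0.0019, and adjusted p = 0.66 with an estimated correlation), and of -0.41 with both terms (camera adjusted p 1.5e-08). Mbp, a main protein of myelin, and Ndrg1 differed by -0.42 and -0.40 (adjusted p 0.14 and 0.096). Adjusted over the list alone, 0 members of either list changed.

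**Figure D2:**
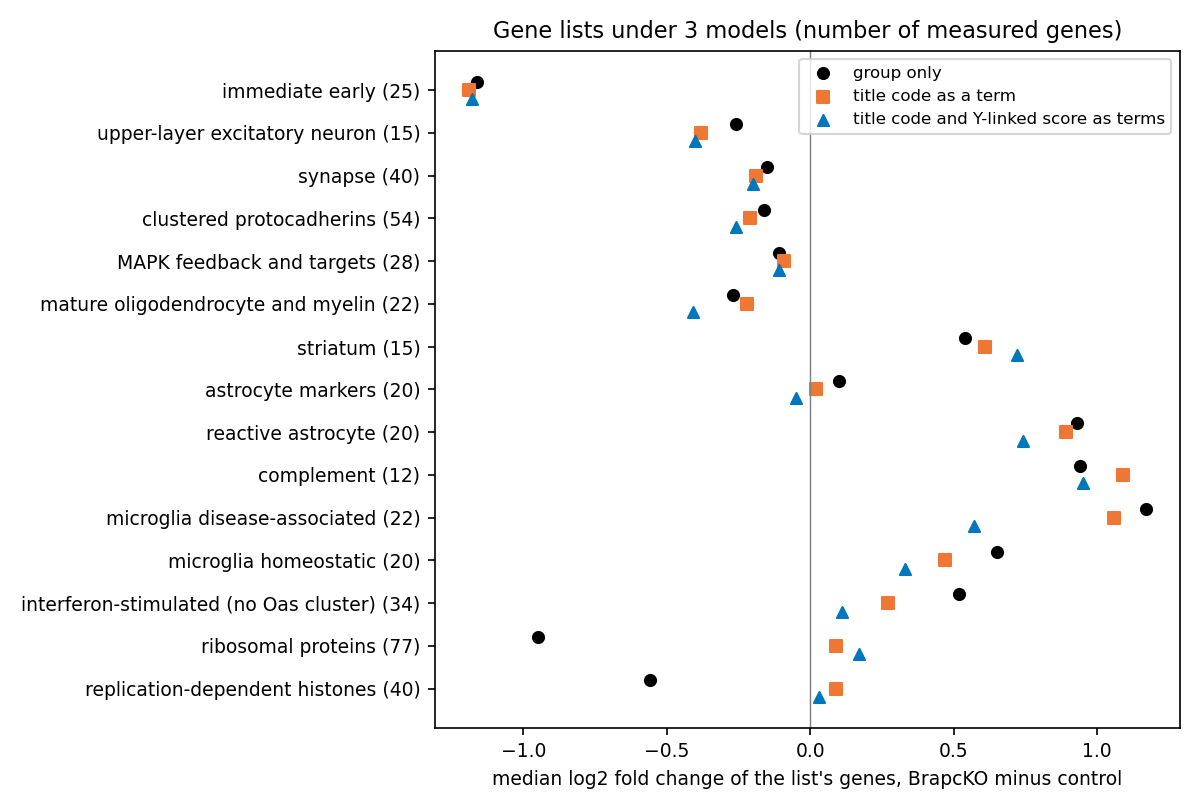
Median log2 fold change (libraries labelled BrapcKO minus control) of 15 gene lists, from 3 models: group only (circles), the title code as a term (squares), and the title code and the Y-linked score as terms (triangles); the number of genes measured stands after each name. The immediate early list lies near -1.16 in all 3 models, and the ribosomal protein list moves from -0.95 with group only to 0.09 and 0.17.

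Senescence, p53, repair and H2A ubiquitin genes were read because Brap encodes a BRCA1-associated ubiquitin ligase. None of the 4 lists was called by camera. Fry called the senescence list (adjusted p 0.034, and 0.035 with the title code as a term). It did not call that list with the Y-linked score or with both terms (0.22 and 0.18). Of 17 genes of senescence and its secretory phenotype 3 rose, 4 when adjusted over the list alone. The rises included those of the metalloproteinase inhibitor Timp2 (0.69, adjusted p 0.0054) and the receptor Tnfrsf1a (0.94, adjusted p 0.038). Tgfb1 differed by 1.18 (adjusted p 0.059, and 0.042 without BrapcKO 04). The senescence median was -0.01 and the mean 0.29 (camera adjusted p 0.13), and the median was 0.37 with the title code as a term (camera adjusted p 0.052). Of 28 p53 targets 1 fell, Psrc1 (-1.11, adjusted p 0.039), also when adjusted over the list alone, and the median was -0.01 and the mean 0.05 (camera adjusted p 0.97). Trp53inp1 differed by 0.40 (adjusted p 0.1). Of 32 genes of double-strand break repair 0 changed (median 0.06, camera adjusted p 0.47), with Topbp1 at 0.28 and Rad51c at -0.44 (adjusted p 0.063 and 0.2). Of 30 writers and erasers of H2A ubiquitin 1 fell, the polycomb protein Cbx6 (-0.27, adjusted p 0.044), and 0 when adjusted over the list alone (median -0.03, camera adjusted p 0.76). Tnfrsf1a lost its call without any 1 of the 5 controls or BrapcKO 06 or 07 (adjusted p 0.066 to 0.087). Psrc1 lost it without any 1 of the libraries except BrapcKO 05 (0.051 to 0.1), as did Cbx6 (0.053 to 0.12). With both terms Tnfrsf1a, Psrc1 and Cbx6 differed by 0.44, -1.33 and -0.30 (adjusted p 0.5, 0.054 and 0.16).

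The largest rise was that of Slc6a5 (ENSMUSG00000039728.15, chromosome 7, 49910146 to 49963856), the glycine transporter of inhibitory nerve endings. It stood at 0.122 ± 0.109 CPM in control and 17.9 ± 12.6 CPM in the libraries labelled BrapcKO, where it ran from 2.44 to 30.8 CPM (7.06, SE 0.88, adjusted p 0.0036). Ctse, the protease cathepsin E, rose by 3.79, the sorting nexin Snx31 by 3.73, the signalling protein Wnt9b by 3.41 and the peroxisomal thiolase Acaa1b by 3.13 (adjusted p 0.028, 0.0071, 0.0089 and 0.014). Pgr15l, the calcium and manganese pump Atp2c2, the lipid-presenting Cd1d1 and Rgs13 rose by 2.94, 2.69, 2.39 and 2.31 (adjusted p 0.009, 0.0023, 0.024 and 0.032). With Itgax these are the 10 largest rises, and all were below 1 CPM in control, where ratios rest on few counts. Without BrapcKO 05 Ctse was 2.67, without BrapcKO 21 Snx31 was 2.98 and Acaa1b 2.47, and without control 22 Rgs13 was 2.91. Ctse lost its call without any 1 of control 09, 22, 23 and 24 (adjusted p 0.057 to 0.074). Cd1d1 lost it without control 08 or 23 or BrapcKO 06 or 07 (0.052 to 0.058), and Rgs13 without any 1 of the libraries except control 22 and BrapcKO 04 and 05 (0.057 to 0.097). With both terms Ctse, Itgax and Cd1d1 differed by 2.11, 2.81 and 2.29 (adjusted p 0.35, 0.28 and 0.096).

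The largest falls beside Egr2, Fos, Cort and Npas4 were those of Rpe65, the retinoid isomerase, and Alox12b, a lipoxygenase. They changed by -2.59 and -2.58 (SE 0.35 and 0.23, adjusted p 0.0031 and 0.00041). Frzb, a secreted antagonist of Wnt, fell from 23.3 ± 5.47 to 5.97 ± 1.8 CPM (-1.97, adjusted p 0.0013). Tcap, Aldh1a7 and Epop changed by -1.98, -1.92 and -1.87 (adjusted p 0.031, 0.0085 and 0.00082). Tcap lost its call without any 1 of the libraries except control 08 and BrapcKO 05 (adjusted p 0.054 to 0.08), and with both terms it differed by -1.87 (adjusted p 0.2).

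The naming rule also took genes for their small p-values after the largest changes were set aside. Fam19a1, a secreted neuronal protein, fell from 67.1 ± 4.85 to 32.2 ± 1.51 CPM (-1.06, SE 0.08, adjusted p 0.00023). Npy1r, a receptor of neuropeptide Y, fell from 34.7 ± 2.51 to 16.9 ± 0.968 CPM (-1.04, SE 0.08, adjusted p 0.00032). Dkkl1, the release factor Cadps2 and the chromatin remodeller Smarca2 changed by -1.47, -0.92 and -0.73, each with an adjusted p of 0.00082. Spata13, a guanine nucleotide exchange factor, rose from 23 ± 1.65 to 48.8 ± 7.4 CPM (1.09, SE 0.11, adjusted p 0.00082). The adaptor Blnk and the synaptic vesicle protein Sv2c rose by 1.75 and 1.14, and Strip2 by 1.56 (adjusted p 0.0009, 0.0013 and 0.0023). With both terms the adjusted p of these 9 genes ran from 0.0014 to 0.014.

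Genes of ribosomal proteins and replication-dependent histones followed the title code. The first principal component held 55% of the variance and separated B1 from B2, and the second held 15.8%. The median ribosomal protein was 2.71 higher in B2 on the log2 scale, and 1907 genes were higher and 1682 lower in B2 than in B1. Between groups the 77 ribosomal protein genes had a median of -0.95 with 0 changed members (camera adjusted p 0.00012, and adjusted p = 0.77 with an estimated correlation), and a median of 0.09 with the title code as a term and 0.17 with both (camera adjusted p 0.0085 and 2e-05). Without BrapcKO 21 it was -1.94. The 40 histone genes had a median of -0.56 with 0 changed members (camera adjusted p 0.004, and adjusted p = 0.76 with an estimated correlation), and 0.09 with the title code as a term (camera adjusted p 0.82). Without control 24 or BrapcKO 04 or 07 the histone list was not called (camera adjusted p 0.11, 0.059 and 0.064), and without BrapcKO 21 its median was -0.89. Adjusted over the list alone, 0 members of either list changed. Of the 47 lists camera called 20, 11 higher and 9 lower; 0 were called with an estimated correlation, also with the title code, the Y-linked score or both as terms, and 10 had the same preset call with each of these terms.

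**Figure D3:**
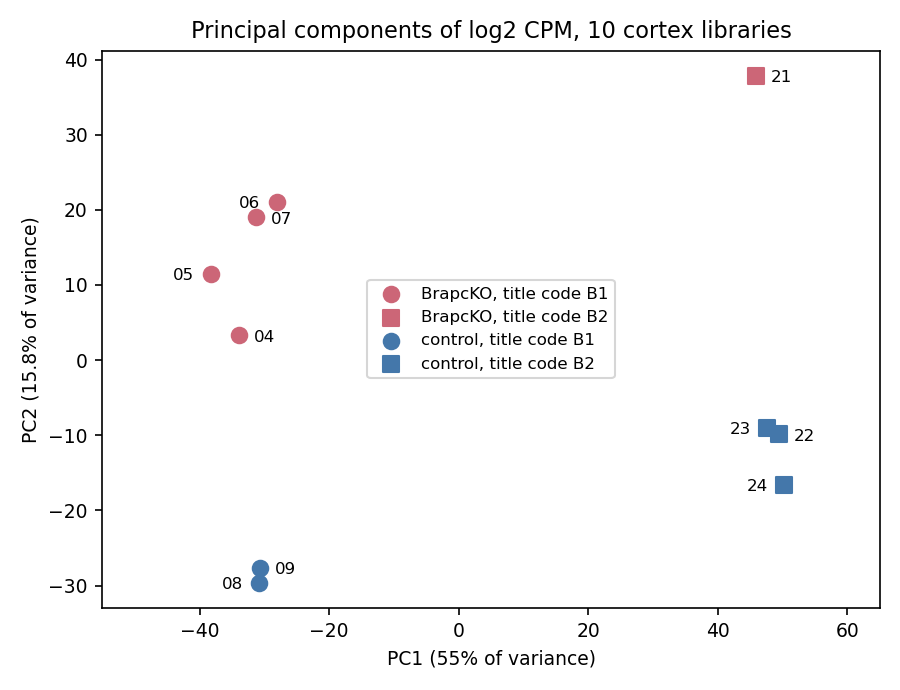
First and second principal components of log2 CPM in the 10 libraries, by group and title code. The first component (55% of the variance) separates B1 from B2, and the second (15.8%) separates the groups within each code.

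Knockout and control genotypes were also compared within each group. Between flox/ko Cre+ and flox/flox Cre+ cortex edgeR called 0 genes, with 682 at an unadjusted p under 0.05, and DESeq2 called 29. The smallest p belonged to Spp1, at 11 ± 1.79 CPM in flox/ko Cre+ (n = 3) and 52.2 ± 27.1 in flox/flox Cre+ libraries (n = 2; -2.25, SE 0.31, edgeR adjusted p 0.26). Vim differed by -0.92 and Fkbp5, a chaperone induced by glucocorticoids, by 0.80 (adjusted p 0.42 and 0.26). Between flox/flox Cre- and flox/wt Cre- cortex edgeR and DESeq2 each called 0 genes, with 338 at an unadjusted p under 0.05 in edgeR. The difference between flox/ko Cre+ and flox/wt Cre- was also set against that between flox/flox Cre+ and flox/flox Cre-. This contrast gave 0 calls in edgeR, with 455 at an unadjusted p under 0.05, and was not run in DESeq2. In simulated data with these group sizes, 72.7% and 80.3% of genes changed 4-fold were called in the 2 comparisons, and 26.9% and 29.9% of those changed 2-fold.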

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

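The tests of wrong labels, of the title code and the Y-linked score, of cell numbers by differences between lists and of handling were chosen after the results were seen; those of BrapcKO 05 and the counts of other splits were not. For the title code and the Y-linked score on lists, the deciding measure (the interval of the difference between library means) was settled after camera, fry and members called had been seen.

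Among 346 groups of 5 libraries, over 126 genes and 47 lists, 42 had 1 library far from the others, where chance gives about 17.3 (1 in 20). BrapcKO 05 accounted for 21 of the 42. The number given for each is the gap to the nearest library of the group over the range of the group. In BrapcKO 05 microglial and immune genes were high: Itgax at 19.94 CPM against 2.248 to 3.941 in the rest (0.904), Ctss at 240.6 against 77.26 to 92.93 (0.904), and C1qa at 172.8 against 55.95 to 71.58 (0.866). The same held for Oasl2 (0.88), Trim30a (0.878), Cxcl16 (0.865), C3ar1 (0.832), C1qc (0.826), Tlr2 (0.824), Ptprc (0.814), Inpp5d (0.805), Lyz2 (0.768) and Gbp3 (0.719). The list means of disease-associated microglia (5.64 log2 CPM against 4.14 to 4.30; 0.893), homeostatic microglia (0.787), cytokines (0.765) and double-strand break repair (0.739) were also highest there. So were Ctse (0.901), Osmr (0.724), Mki67 (0.717) and Tcap (0.713).

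BrapcKO 21, the only B2 library of its group, was highest for Rpl37 (0.947), Rps15 (0.857), Rpl13a (0.823), Rpl30 (0.726), the ribosomal protein list (6.36 log2 CPM against 3.54 to 3.60; 0.979) and Snx31 (0.789). It was lowest for Rph3a (0.724) and the list of meninges and fibroblasts (0.732). BrapcKO 04 was highest for Kcnj8 (0.848), Ly6a (0.711) and the MAP kinase list (0.824), and lowest for the Y-linked genes (0.983). Control 23 was highest for the Y-linked genes (0.917). Control 24 was highest for Cplx2 (0.902) and Stx1a (0.843) and lowest for Ctss (0.778) and Sv2c (0.771). C3ar1 was highest in control 08 (0.75), Slc2a1 in control 09 (0.857) and Rgs13 in control 22 (0.765).

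Brap was not lower in the libraries labelled BrapcKO. Single wrong or swapped labels are argued against, since 0 of the 10 libraries lay nearer to the other group on genes called without them; control 23 came closest, at a distance of 18.3 from its own group and 22.3 from the other. A fall hidden by the title code and the uneven Y-linked reads is argued against by the log2 fold change of 0.30 with both terms. A deletion of part of the gene that leaves the rest transcribed stays open, because the whole-gene value of 0.23 holds no count per exon. Recombination in only part of the cortical cells was not tested for the flox/flox Cre+ libraries. In flox/ko Cre+ libraries it would still leave the ko allele deleted. Brap stood there at 109.9, 110.5 and 108.8 CPM, and at 88.1, 76.7 and 84.2 CPM in flox/wt Cre- libraries. These values argue against partial recombination as the whole cause in flox/ko Cre+ libraries, if the ko allele gives no reads. The labels do not state whether it does.

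The disease-associated microglia and reactive astrocyte lists were higher in the libraries labelled BrapcKO. BrapcKO 05 alone does not account for this: without it the medians were 0.44 and 0.94, although the microglial median was 1.17 with it. More microglia of unchanged profile are argued against as the whole cause. The disease-associated mean minus the homeostatic mean was -0.40 ± 0.25 in control and 0.02 ± 0.16 in BrapcKO (n = 5 each, exact permutation p = 0.00794, the smallest that 252 arrangements can give). The ranges nearly met (-0.71 to -0.15 and -0.13 to 0.27), and the arrangements did not hold the title code fixed. Within control the disease-associated mean was lower in B1 (3.46 and 3.26) than in B2 (3.65, 3.67 and 3.70). With the title code and the Y-linked score as terms the astrocyte library mean was 0.64 higher (95% interval 0.20 to 1.08, and 0.97 higher with group only). This argues against these as the whole cause there if their effects add. That could not be checked, since no B1 control had Y-linked reads and no B2 BrapcKO library was without them. Only 1 of the 9 called members was called with both terms (list median 0.93 and 0.74, adjusted p 0.42 with an estimated correlation and 0.12 with fry). The disease-associated mean was 0.76 higher (95% interval -0.43 to 1.95; 0.95 with group only), so for that list the title code and the Y-linked reads cannot be told apart from the group, because the interval holds 0. The knockout, the presence of Cre in every BrapcKO library and no control, and other differences that the labels do not give stay open.

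The immediate early list was lower in the libraries labelled BrapcKO. Fewer neurons or less neuronal RNA are argued against as the whole cause, since the immediate early mean minus the synapse mean was -3.68 ± 0.29 in control and -4.50 ± 0.22 in BrapcKO (n = 5 each; exact permutation p = 0.00794, the smallest of 252 arrangements). The title code and the Y-linked score are argued against as the whole cause by the same measure, again if their effects add. The mean was lower by 1.00 with both as terms (95% interval -1.62 to -0.37, and lower by 0.97 with group only). In the main fit 16 members were called lower, and 10 with both terms (list adjusted p 0.42 with an estimated correlation and 0.12 with fry). Immediate early genes respond to handling within minutes, and a difference in handling or time of day between the groups could also lower them. The circadian list had a median of -0.28, but no time of collection is given, so handling and genotype cannot be told apart here. Nor can Cre itself be told apart from the knockout.

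The counts of calls were set against other splits of the libraries. Of 100 splits of the 10 libraries into 5 and 5, 5 gave at least as many genes as the real one (617), so chance is not excluded by this count; the highest other gave 1987. All 4 other splits placed 5 of the 6 B1 libraries on one side, which points to the title code as a structure of the libraries, and the highest of the splits that did not was 4. With the title code as a term, only the real one of 60 splits within the codes reached its count (1152), and the highest other gave 10. That is the smallest share that 60 splits can give, so chance is made unlikely there but not excluded. The Y-linked score was not a term in these splits, and with both terms the real count was 322. For the gene lists, 16 of 100 splits gave at least the 20 lists of the real one and the highest other gave 23, so chance is not excluded for that count. Within the codes 7 of 60 splits gave at least the real 22 lists, and the highest other gave 29. The real split alone reached its list median, in absolute size, for the immediate early, reactive astrocyte, disease-associated microglia and complement lists, among others. A median as large came from 11 splits for homeostatic microglia, 12 for cell cycle and 13 for myelin, the real one included. It came from 14 for MAP kinase targets, 16 for endothelium and 26 for interferon-stimulated genes.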

How the results depend on the processing

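The fit with both the title code and the Y-linked score, the fits of the lists with the Y-linked score, those with terms and an estimated correlation or fry, and the alternatives for the genotype comparisons were chosen after the data were seen.

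The number of genes called, 617, was 1186 with DESeq2, 3088 with limma-voom and quality weights, 1152 with the title code as a term and 1249 with 1 surrogate variable. It was 94 with the Y-linked score, 322 with both terms, 191 in the test against a fold of 1.2, 103 between flox/ko Cre+ and flox/wt Cre- libraries and 4 between flox/flox Cre+ and flox/flox Cre- libraries. Those 4 were Ddx3y, Uty, Kdm5d and Eif2s3y, all Y-linked and named after their values were seen. In that pair both Cre+ libraries had Y-linked reads and neither Cre- library did. Leaving out 1 library gave 275 (control 23) to 600 (BrapcKO 05). The 2 genotype subsets hold fewer libraries and the fold test a stricter threshold; for the others the cause was not tested. The other scalings, tests and filters gave 577 to 865, the B1 libraries alone 416, and the default filter removed no gene, so the fit without it tested nothing.

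Brap was 0.32 and called with quality weights (limma adjusted p 0.016), whereas its adjusted p ran from 0.089 to 1 in all other alternatives, and it was -0.03 in the flox/flox pair. Of 3493 values of the 125 other named genes under alternatives, 3485 had the main direction, and none of the called genes reversed. All these fits reuse the same libraries, and many of the genes were picked for their difference in them, so this is little support. Of the 66 called genes of the naming rule, 43 were called without each library in turn and 23 were not. Of the 20 lists called, 0 were called with an estimated correlation, with or without terms. With fry 10 of the 47 lists were called, 8 of them among the 20, the others being the inhibitory neuron and senescence lists. Fry called 10 with the title code, 1 with the Y-linked score (immediate early) and 0 with both as terms. The histone list was 0.09 with the title code as a term, the ribosomal protein list 0.09 with it and 0.17 with both terms, and the oxidative phosphorylation list 0.12 and 0.14; the cause was not tested beyond their difference between the codes.

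Between flox/ko Cre+ and flox/flox Cre+ libraries DESeq2 called 29 genes, and leaving out 1 library gave 0 to 42 (without BrapcKO 06, which leaves 1 flox/flox Cre+ library, assumed to vary like the others). Between the control genotypes leaving out 1 library gave 0 to 1 (Gm14295, without control 23, named after its values were seen). The alternatives for normalised values did not apply to counts. No paired analysis was possible because the groups share no replicate numbers. Genes below about 1 CPM rest on few counts, and the depth limits their ratios.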

Other observations

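The test of recurrence between genotype pairs was written before its result was seen; the genes near Brap were picked after their values were seen.

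Vascular and proliferation genes were higher as lists in the libraries labelled BrapcKO. The 20 endothelial genes had a median of 0.35 with 0 changed members and the 14 mural genes 0.29 with 1, Notch3, a receptor of pericytes and smooth muscle (0.71, adjusted p 0.045). Camera adjusted p-values were 0.0011 and 0.014, and adjusted p = 0.64 and 0.53 with an estimated correlation. They were 0.052 and 0.11 with the title code as a term (endothelial median 0.19), 5e-06 and 0.0052 with the Y-linked score (endothelial median 0.53), and 0.0026 and 0.13 with both. Vwf, the clotting factor of endothelium, stood at 20.2 ± 4.63 and 58 ± 34.7 CPM (1.52, adjusted p 0.071, and 0.024 without BrapcKO 21). The 27 cell cycle genes had a median of 0.45 with 0 changed members (camera adjusted p 0.0025, and adjusted p = 0.64 with an estimated correlation), with Cenpf at 1.26 (adjusted p 0.054, and 0.031 without BrapcKO 04). The cell cycle list was not called with the Y-linked score (median 0.25, camera adjusted p 0.069) or with both terms (0.20 and 0.1). Without BrapcKO 05 the cell cycle median was 0.25 (camera adjusted p 0.031), and without BrapcKO 04 the endothelial median was 0.23 (0.011). Notch3 lost its call without any 1 of the libraries except BrapcKO 21 (adjusted p 0.058 to 0.11), and with both terms it differed by 0.49 (adjusted p 0.2).

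Clock, glucocorticoid and cytokine genes differed as lists too. The 17 circadian genes had a median of -0.28 with 1 fall, Bhlhe40, a repressor of the clock (-0.67, adjusted p 0.019), and Hlf at -0.52 (adjusted p 0.13, and 0.048 without control 24). The 16 glucocorticoid response genes had a median of 0.31 with 0 changed members, with Map3k6 at 0.79 and Fkbp5 at 0.55 (adjusted p 0.087 and 0.15). The 15 cytokine and NF-kB genes had a median of 0.26 with 1 rise, the chemokine Cxcl16 (1.80, adjusted p 0.03). Camera adjusted p-values were 0.0066, 0.027 and 0.02, and adjusted p = 0.34, 0.66 and 0.4 with an estimated correlation. They were 0.003, 0.023 and 0.032 with the title code as a term and 0.058, 0.0016 and 0.098 with the Y-linked score. With both terms the medians were -0.14, 0.51 and 0.12 (camera adjusted p 0.03, 0.00022 and 0.2), and Bhlhe40 and Cxcl16 differed by -0.74 and 1.02 (adjusted p 0.064 and 0.4). Bhlhe40 lost its call without control 23 or BrapcKO 06 or 07 (adjusted p 0.052 to 0.056), and Cxcl16 without control 09, 22, 23 or 24 or BrapcKO 06 (0.054 to 0.071). The glucocorticoid list was not called without control 22 or BrapcKO 04, 07 or 21 (camera adjusted p 0.057 to 0.11), and its median ran from 0.15 (without BrapcKO 04) to 0.43.

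In the main fit camera did not call the remaining lists. Medians and adjusted p were 0.40 and 0.09 for antigen presentation, 0.10 and 0.57 for oligodendrocyte precursors, 0.07 and 0.13 for the proteasome, -0.29 and 0.14 for heat shock, and 0.00 and 0.97 for the unfolded protein response. They were -0.05 and 0.19 for YAP targets, -0.06 and 0.96 for polycomb targets, -0.05 and 0.86 for progenitors, 0.03 and 0.86 for cholesterol synthesis, 0.11 and 0.091 for lysosomes, -0.08 and 0.23 for oxidative phosphorylation, and 0.14 and 0.34 for the mitochondrial genome. Lists of other tissues or regions gave -0.02 and 0.8 for meninges, -0.88 and 0.13 for choroid plexus, -0.45 and 0.083 for hippocampus, 0.07 and 0.71 for thalamus, -0.38 and 0.34 for erythrocytes, and 0.34 and 0.29 for peripheral immune cells. The Y-linked genes had 2.07 and 0.13.

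Terms and single libraries changed the calls of some of these lists at the preset correlation; with an estimated correlation none of the 47 lists was called with any of the terms. With the title code as a term camera called the proteasome (median 0.22, adjusted p 9.3e-08), oxidative phosphorylation (0.12 and 0.00028), cholesterol (0.12 and 0.032) and lysosome lists (0.10 and 0.049) higher and the hippocampus list lower (-0.37 and 0.031); adjusted p = 0.53, 0.65, 0.72, 0.65 and 0.65 with an estimated correlation. With both terms it called the proteasome (0.26 and 4.3e-08) and oxidative phosphorylation (0.14 and 2.4e-05) lists higher and the erythrocyte list lower (-2.30 and 0.00047); adjusted p = 0.49, 0.71 and 0.42 with an estimated correlation. With the Y-linked score alone the oxidative phosphorylation (-0.15 and 0.045) and erythrocyte (-1.53 and 0.015) lists were lower (adjusted p = 0.83 and 0.55 with an estimated correlation). The choroid plexus list was called without control 09 or 22 or BrapcKO 04 (adjusted p 0.018, 0.008 and 0.033; median -1.14 without BrapcKO 04), and without control 24 its median was -0.01 (0.94). The hippocampus list was called without control 09 or BrapcKO 04 or 07 (adjusted p 0.037, 0.028 and 0.018), and without BrapcKO 21 its median was -0.16 (0.72). Without 1 library the erythrocyte median ran from -1.3 to -0.08, and the list was called without control 22 (0.046). Antigen presentation was called without control 22 or 23 or BrapcKO 06 or 21 (adjusted p 0.021 to 0.049), and its adjusted p was 0.31 without BrapcKO 05. Its median ran from 0.22 to 0.48 when each library was left out in turn. The proteasome was called without control 22 or 24 or BrapcKO 05 (0.0042 to 0.037), and its median ran from 0.01 to 0.14. Oxidative phosphorylation was called lower without control 08 or 09 or BrapcKO 21 (0.00068 to 0.028), and its median ran from -0.17 to 0.02. Heat shock was called without BrapcKO 21 (adjusted p 0.0099), and its adjusted p was 0.38 without BrapcKO 05, with medians from -0.45 to -0.14. Lysosomes were called without control 24 or BrapcKO 04 (0.033 and 0.029), and the Y-linked genes without control 23 or BrapcKO 04 (0.039 and 2.1e-06).

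Of 24 genes near Brap on chromosome 5, 2 fell and 0 rose, with a median of 0.02 (camera adjusted p 0.86). Rph3a, a synaptic vesicle protein at 120940499 to 121010092, fell from 277 ± 59.4 to 158 ± 18.8 CPM (-0.82, SE 0.14, adjusted p 0.01). Aldh2, an aldehyde dehydrogenase of mitochondria at 121566027 to 121593824, changed by -0.56 (SE 0.14, adjusted p 0.045), and it differed by -0.30 with both terms (adjusted p 0.37).

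The difference between the libraries labelled BrapcKO and control may recur between genotype pairs that share no library. Of the 103 genes called between flox/ko Cre+ and flox/wt Cre- libraries, 97 (94.2%) had the same direction between flox/flox Cre+ and flox/flox Cre- libraries, against 68.4% of all genes. The title code and the Y-linked reads are unevenly spread in both pairs, so part of the shared direction may come from them. In the flox/flox pair BrapcKO 05 and 06 had Y-linked reads and control 09 and 24 did not. There the Y-linked reads cannot be told apart from the group. Both pairs also set Cre+ against Cre- libraries. Where both were matched, the immediate early mean differed by -0.64 in B1 libraries without Y-linked reads (2 control and 1 BrapcKO) and by -1.36 in B2 libraries with them (1 and 1), with no test at these numbers. In the same sets the reactive astrocyte mean differed by 0.61 and 0.59 and the disease-associated microglia mean by 0.86 and 0.47. Several of these values, and others, disagreed in size or sign: complement differed by 1.09 and 0.22, interferon-stimulated genes by 0.17 and -0.04, antigen presentation by 0.59 and -0.40, cell cycle by -0.20 and 0.64, and hippocampus by 0.26 and -1.02.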
